A study of Mus musculus with 386 samples.

How the data were processed

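Female germ cells were picked by hand from enzymatically dissociated mouse ovaries at E17.5, P2.5 and P6.5, per the labels, and 1 library was made per cell with Smart-seq2 and a KAPA HyperPlus kit. Libraries were sequenced on a NovaSeq-6000 instrument with 150-base paired reads, per the labels' protocols. The authors deposited a table of raw counts per gene and a table of FPKM values, which divide by gene length and library size, each with 1 column per cell. STAR 2.7.10b, HTSeq 0.13.5, RSEM 1.3.3 and the build mm10 are named in the submitters' processing notes, and which tool made which table is not given in the sources used here. The gene annotation, the strand setting, the treatment of reads that map to several genes and the amount of spike-in per cell are not given in the sources used here either. The deposited counts hold 54750 rows, of which 54658 are genes and 92 are ERCC spike-in RNAs. The deposited FPKM columns sum to between 639030 and 1255800.

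Each column was joined to its library by the name in the labels, and 0 columns belonged to no library in the labels. The counts of 384 libraries matched their own FPKM column best by Pearson correlation of log values, and those of E17.5 libraries 4 and 7 matched another library's column slightly better (0.808 against 0.798 and 0.801 against 0.763). Counts were the main measure throughout. Spike-in rows were left out of library sizes and took 1.18%, 0.226% and 0.0296% of counts at the 3 stages. Rows of genes with a close copy, such as the Nlrp, Oas1, globin and ribosomal protein families, can share reads, and their split between copies is uncertain.

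Pairs of libraries that were each other's nearest neighbour by Pearson correlation of log counts were compared. The comparison used a chi-square per gene over genes with a summed count of at least 20. In 24 pairs of P2.5 libraries the median chi-square was 0.686 to 1.03, against 0.455 from sampling alone. It had a median of 34.5 (lowest 3.39) in 300 other P2.5 pairs drawn at random. Another 19 nearest-neighbour pairs were not counted as 1 cell, and the lowest value among them, of a P2.5 pair, was 2.315. The same spike-ins were present or absent in a median of 93.8% of 32 informative spike-ins in these pairs, against 64.1% in other pairs. The ranges overlapped, with a lowest share of 68.8% in these pairs and a highest of 93.8% in other pairs. Each pair below a limit of 1.5 was summed as 1 cell, which turned the 317 P2.5 libraries into 293 cells. Cells were kept with at least 100000 counts and 2000 genes, which removed 0. No doublet caller was run on these hand-picked cells, and markers of other cell types were used in its place.

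Counts were summed over the cells of a stage and scaled to counts-per-million (CPM). A gene was measured in a comparison when it had at least 1 CPM in either stage sum and a count in at least 3 cells. The log2 ratio of a named gene is that of the CPM values with an exact conditional Poisson 95% interval. Lists, counts of 2-fold members and alternative settings used the ratio after adding 0.5 CPM to both stages. Shares of cells have exact Clopper-Pearson intervals. A share of 0 is given with the upper bound of that interval. Reads without molecular identifiers are not independent molecules, so the intervals of ratios cover the counting of reads only and are too narrow for molecules. The intervals of shares treat the cells of a stage as independent draws and do not cover differences between animals. No test was made, because the labels name no animals and cells of 1 stage are not replicates.

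Fixed before the data were examined were 18 gene lists of pathways, 8 lists of cell type markers and 3 lists of oocyte state markers. The ribosomal protein and mitochondrially encoded lists were set by a pattern of the gene symbol. The other lists hold 379 genes, of which 6 are absent from the rows. A list's median was placed among the medians of 10000 random lists of equal size drawn within 20 bins of mean expression (seed 1). Marker lists were counted as seen in a cell with at least 10 counts after thinning the cell to 100000 counts. The rule for named genes was also fixed. It took the 12 genes with the highest and the 12 with the lowest ratio per comparison among those with at least 20 CPM and a count in 50% of cells of the higher stage and a 2-fold difference in the mean over cells. It left out unnamed gene models, pseudogenes and mitochondrial genes. Per list it added up to 2 members at either end with at least 5 CPM, plus Ddx4 and Dazl. Genes outside it are said to be chosen after their values were seen.

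P2.5 cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 after leaving out every list gene. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes were scaled with values limited to 10. Leiden clustering at resolution 0.5 ran on 20 principal components and 15 neighbours. Each cluster's summed counts were compared with those of all other P2.5 cells. Gene coordinates are 1-based and come from GENCODE release M21, in which 54106 gene rows (99.0%) found their symbol. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

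Stage ratios, list percentiles, the chi-square of pairs and the clustering were tested on simulated data, and the other steps were not. For P2.5 over E17.5 (15775 genes) genes changed 2-fold and 4-fold were recovered with a median absolute error of 0.20 and 0.20 in log2 units and 100% of directions. For P6.5 over P2.5 (14224 genes) the errors were 0.12 and 0.11, with 100% of directions. The changed genes had at least 5 CPM at the earlier stage, spread was drawn separately for each gene and cell, and no library held RNA of another cell. The errors therefore do not cover genes below that level at E17.5, such as Padi6 and Zp1, or libraries with such RNA. The intervals were checked on separate counts drawn with counting error alone, where 96.5% and 94.0% held the true ratio in the first and second comparison. That check had no spread between cells, so it does not show that the intervals cover such spread. A list raised 2-fold reached percentile 100 in both, and an unchanged list lay at 22.3 and 45.0. Of 20 libraries split in 2 by simulation 20 fell under the limit for pairs, and 0 of 20 simulated separate cells did. The split libraries differed by sampling alone, unlike the real pairs, so the check says little about pairs near the limit. Finding nearest neighbours was not part of it. With 200 genes changed 4-fold the clustering found both groups (adjusted Rand index 1), and with none changed it still gave 2 clusters.

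Alternative settings covered the mean over cells, edgeR 4.0.16 TMM and DESeq2 1.42.0 median-of-ratios scaling of the stage sums, other filters on genes and cells, thinning, FPKM, 5 CPM added, cells left out by depth, number or somatic markers, and other clustering settings. Added after the data were seen were 1 library of each pair, rRNA rows left out, E17.5 without the 4 libraries whose germ cell markers lay under 25% of the stage median, E17.5 cells 1 to 10 and 11 to 22 alone, spike-in scaling, clustering with pairs kept apart or without rRNA rows, and the same clusters without P2.5 cells above 10 on the second principal component.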

Results

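Single germ cells of the mouse ovary were profiled before birth at E17.5 and after birth at P2.5 and P6.5 (days of embryonic or postnatal life) with Smart-seq2, a method that copies and amplifies polyadenylated RNA from 1 cell. Around the first of these ages oocytes pass through meiotic prophase in clusters of germ cells. After birth each surviving oocyte is enclosed in a primordial follicle, where it either stays dormant or starts to grow. The series title asks which gene networks go with that choice of fate. The labels name a stage for each library and no animal, litter or pool, so each stage was treated as 1 sample made of many cells. There is therefore no replicate check and no test of any difference. Intervals of ratios cover the counting of reads only, and intervals of shares treat the cells of a stage as independent draws.

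Of the 386 libraries, 22 were from E17.5 and 47 from P6.5, and all others from P2.5. Among the P2.5 libraries, 24 pairs differed less than the other pairs compared and were each counted as 1 cell, which left 362 cells in all. Their median chi-square of 0.686 to 1.03 was above the 0.455 of sampling alone and far below the median of 34.5 in pairs drawn at random. The closest pair not counted as 1 cell stood at 2.315. Gene counts per library ran from 1.02e+06 to 1.61e+07 at E17.5 (median 6.39e+06), from 4.36e+05 to 2.398e+07 at P2.5 (median 6.18e+06) and from 5.71e+06 to 1.58e+07 at P6.5 (median 8.60e+06). Summed over cells the stages held 141253010, 2280427479 and 409164954 counts. Between 9607 and 19526 genes had a count in a library. Every cell passed the filter of at least 100000 counts and 2000 genes.

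The amount of RNA per cell, read against external spike-in RNA, was higher at each later stage. The median number of gene counts per spike-in count was 81.3 at E17.5 (quartiles 58.6 to 112.03), 465 at P2.5 (307.8 to 726) and 3204 at P6.5 (2662 to 4329). These medians were 5.72-fold apart between E17.5 and P2.5 and 6.89-fold apart between P2.5 and P6.5, and 97.3% of P2.5 cells lay above every E17.5 cell. The scale assumes that each cell received the same amount of spike-in, an amount not given in the sources used here.

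**Figure D1:**
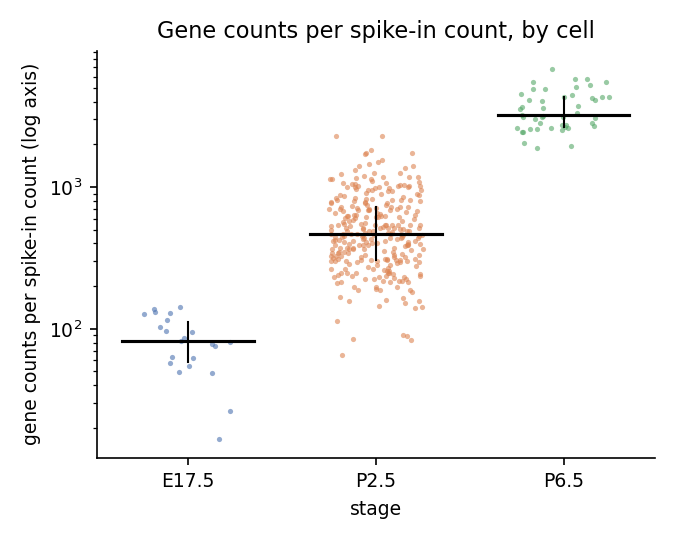
Gene counts per spike-in count of each cell (points, log axis) at E17.5 (22 cells), P2.5 and P6.5 (47 cells), 362 cells in all; the horizontal line is the median and the vertical line spans the quartiles. The medians are 81.3, 465 and 3204, and 44 of 47 P6.5 cells lie above every P2.5 cell.

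Germ cell markers were high in most libraries of every stage, and markers of most other ovarian cell types were highest at E17.5. The germ cell list (Ddx4, Dazl, Dppa3, Mael, Taf4b, Sycp3) held 2833, 4019 and 5175 counts-per-million (CPM) in the E17.5, P2.5 and P6.5 sums, and all 362 cells had at least 10 counts of it after thinning to 100000 counts. By the same measure granulosa and pregranulosa markers were seen in 9 of 22 E17.5 cells (40.9%, exact 95% interval 20.7 to 63.6%), 11 P2.5 cells (3.75%, 1.89 to 6.62%) and 1 of 47 P6.5 cells (2.13%, 0.0539 to 11.3%). Erythroid markers, mostly globin transcripts, were seen in 22 of 22 E17.5 cells, 26 P2.5 cells (8.87%, 5.88 to 12.7%) and 0 of 47 P6.5 cells (up to 7.55%). The erythroid list held 1593, 38.7 and 1.94 CPM of the 3 sums. Stroma markers were seen in 5, 13 and 2 cells of the 3 stages, endothelium markers in 4, 10 and 0, surface epithelium markers in 6, 4 and 0, immune markers in 2, 0 and 0, and perivascular markers in 0, 1 and 0.

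Germ cell markers were low in 4 E17.5 libraries (numbers 8, 10, 15 and 16), at 488, 300, 246.6 and 705 CPM against a median of 3851 CPM in the other 18. These libraries held 30% of the E17.5 counts. Library 10 had 12.5% of its counts on 12 mast cell genes, and library 16 had 1402 CPM of granulosa and pregranulosa markers against a median of 103.2 CPM in the other 18. Counts led with for E17.5 are therefore also given without these 4 libraries, a choice made after the data were seen.

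Of the 18 pathway lists, 2 differed most between E17.5 and P2.5, oocyte growth with the egg coat and the subcortical maternal complex. Most genes of oocyte growth and the egg coat were low at E17.5 and higher at P2.5, with 28 of 30 measured members at least 2-fold higher at P2.5 and 0 at least 2-fold lower. All 8 measured members of the subcortical maternal complex, a protein assembly that the egg stores for the embryo, were at least 2-fold higher at P2.5, as were 8 of 14 members of the oocyte transcription factor list, which also holds other regulators such as the Notch ligand gene Jag1. As a share of counts, 24 of 36 meiotic prophase genes were at least 2-fold lower at P2.5 and 0 at least 2-fold higher, whereas per spike-in count 10 were lower and 15 higher. Without the 4 libraries low in germ cell markers, as a share of counts, 28 growth and egg coat genes, 8 members of the complex and 7 of the transcription factor list were at least 2-fold higher. Of the meiotic prophase genes 27 were then at least 2-fold lower.

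The level of a gene is its CPM in the summed counts of a stage. The median log2 ratio of all 17421 measured genes, P2.5 over E17.5, was −0.26, and other scalings moved that median by 0.35 (TMM), 0.22 (median-of-ratios), 0.22 (the deposited FPKM) and 2.51 (spike-in). List medians are followed by their value relative to all genes and by their percentile among 10000 random lists matched on expression.

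The growth and egg coat list had a median log2 ratio of 4.25 (4.51 relative to all genes, percentile 100), and the subcortical maternal complex list one of 5.30 (5.56 relative to all genes, percentile 100). The size of both depended on the E17.5 libraries used. The summed growth level had a median of 154.7 CPM in E17.5 libraries 1 to 10 and 6.25 CPM in libraries 11 to 22, and the list median was 3.22 against the first set (27 of 32 members at least 2-fold higher and 3 lower) and 6.24 against the second (29 of 30 and 0). The subcortical maternal complex median was 4.53 and 7.20. Padi6, an oocyte protein of the peptidylarginine deiminase family that is needed for cytoplasmic lattices, stood at 0.821 CPM at E17.5 and 3567 CPM at P2.5, a log2 ratio of 12.09 (95% interval 11.82 to 12.36), and its per-cell median was 0 at E17.5 and 2815 CPM at P2.5 (quartiles 1952 to 4096). All of its E17.5 counts lay in libraries 1 to 10. The gene (ENSMUSG00000040935.12) lies on the minus strand of chromosome 4, 140727355 to 140742643, in GENCODE M21, which annotates the build that mm10 names. Nlrp5, another member of the complex (ENSMUSG00000015721.18, chromosome 7, 23385889 to 23441922, plus strand), stood at 0.517 and 1818 CPM (log2 ratio 11.78, 11.45 to 12.13). The zona pellucida genes Zp1 and Zp3, which encode proteins of the egg coat, stood at 0.156 and 1.18 CPM at E17.5 and at 492 and 750 CPM at P2.5 (log2 ratios 11.63 and 9.31). Zp3 is ENSMUSG00000004948.12, chromosome 5, 135980099 to 135988624, plus strand. Nlrp14, Oas1h, Musk, Unc13c, Abi3bp and Xdh, together with Th, the first enzyme of catecholamine synthesis, and the homeobox gene Noto, made up the rest of the 12 genes with the largest ratios, with P2.5 levels of 204.5 to 916 CPM. Among growth genes with at least 5 CPM, Fmn2 (log2 ratio 0.54, and −0.26 with E17.5 cells 11 to 22 alone) and Bmp15 (2.85) had the smallest ratios.

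Oocyte transcription factors had a median log2 ratio of 1.51 (1.77 relative to all genes, percentile 99.99). Tbpl2, a TATA-binding protein relative that oocytes use in place of the general factor, had 1 count at E17.5 and stood at 65.9 CPM at P2.5, a ratio of 9310 with an interval of 1671 to 367730. Jag1 stood at 6.64 and 88.6 CPM (log2 ratio 3.74). Taf4b, a gonadal subunit of the general factor TFIID, was lower at P2.5 than at E17.5, at 108.9 against 307.2 CPM (log2 ratio −1.50).

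The meiotic prophase list had a median log2 ratio of −1.90 (−1.64 relative to all genes, percentile 0), which became 0.61 per spike-in count. Stra8, the retinoic acid target gene needed to start meiosis (ENSMUSG00000029848.11, chromosome 6, 34920163 to 34939344, plus strand), stood at 82.7 CPM at E17.5 and 0.0952 CPM at P2.5 (log2 ratio −9.76, interval −9.96 to −9.57). Meioc, which keeps the meiotic programme running (ENSMUSG00000051455.13, chromosome 11, 102663716 to 102682237, plus strand), stood at 255.3 and 0.804 CPM (log2 ratio −8.31, −8.38 to −8.24). Each of these 2 genes stayed below its E17.5 level per spike-in count as well, since the spike-in shift was 2.51. Rec114 (log2 ratio 1.01) and the synaptonemal complex gene Syce1 (0.66) were higher at P2.5. Summed over the list, the per-cell level had a median of 7749 CPM at E17.5 (quartiles 4727 to 9570) and 3114 CPM at P2.5 (2764 to 3564), and no P2.5 cell reached the E17.5 median, which allows a share of up to 1.25%.

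Glycolysis, cholesterol and lipid synthesis, and immediate early genes had lower medians at P2.5 as a share of counts and higher ones per spike-in count, and their values depended on the 4 libraries low in germ cell markers. For 2 of these lists the summed level per cell went the other way, with medians of 2195 CPM at E17.5 and 5123 CPM at P2.5 for glycolysis and of 909 and 1496 CPM for cholesterol and lipid synthesis. Glycolysis had 10 of 17 members at least 2-fold lower and a median of −1.36 (−1.10 relative to all genes, percentile 0), against 6 members and −0.32 without those libraries and 1.15 per spike-in count. Within it, Ldhb stood at 90.6 and 2994 CPM (log2 ratio 5.05), and Ldha, the other main lactate dehydrogenase subunit, at 788 and 35.8 CPM (−4.46, or −2.87 without those libraries). Cholesterol and lipid synthesis had 9 of 19 members at least 2-fold lower and a median of −0.98 (−0.72 relative to all genes, percentile 0.28), against 3 members and −0.59 without them and 1.54 per spike-in count. Its squalene synthase gene Fdft1 was higher at P2.5 (97.7 and 651 CPM, 2.73) and its desaturase gene Scd2 lower (79.2 and 3.97 CPM, −4.32). The immediate early and heat shock list had 10 of 16 members at least 2-fold lower and a median of −1.49 (−1.23 relative to all genes, percentile 0.01), against 7 and −0.97 without them and 1.03 per spike-in count. Jun stood at 167.7 and 11.8 CPM (−3.83) and Fos at 14.8 and 51.7 CPM (1.81).

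The other lists had members on both sides. In the quality control and cell death list (median −0.38, percentile 15.5, positive per spike-in count) 3 of 21 members were at least 2-fold higher at P2.5 and 9 lower. Its Trp63, whose product removes oocytes with unrepaired DNA breaks, stood at 5.10 and 257.2 CPM (log2 ratio 5.66, 5.55 to 5.76). In the DNA methylation list (median 0.38, percentile 83.2) 4 of 12 members were higher and 2 lower, and Dppa3, which shields the maternal genome from demethylation after fertilisation, stood at 90.3 and 2165 CPM (4.58). In the piRNA list (median 0.07, percentile 49, and −0.37 without the 4 libraries) 5 of 18 were higher and 2 lower, with Gtsf1 at 27 and 709 CPM (4.71). The KIT, PI3K, mTOR and FOXO list had 6 of 25 higher and 2 lower (median 0.03, percentile 44.6, below 0 with E17.5 cells 11 to 22 alone), with the mTOR inhibitor gene Deptor at 19.8 and 157.98 CPM (2.996) and Akt1 at 6.30 and 29.6 CPM (2.23). Stored mRNA regulators had 6 of 20 higher and 2 lower (median 0.29, percentile 82.7, and −0.01 without the 4 libraries), with Zar1 at 0.566 and 26.7 CPM (5.56) and the uridylyltransferase gene Tut4 at 64.6 and 8.04 CPM (−3.01).

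Primordial germ cell and pluripotency genes had 4 of 15 members at least 2-fold higher and 9 lower (median −1.22, percentile 12.5), a median that was positive per spike-in count and with E17.5 cells 1 to 10 alone, and the summed level per cell was higher at P2.5 (medians 90.3 and 199.2 CPM). The mitotic list had 4 of 22 higher and 5 lower (median −0.49, percentile 0.30, positive per spike-in count), with Top2a at 398 and 37.8 CPM (−3.40) and Cdk1 at 85.5 and 232.1 CPM (1.44). Autophagy had 5 of 18 higher and 1 lower (median 0.32, percentile 82.5), and oxidative phosphorylation 6 of 23 higher and 0 lower (0.54, percentile 96.3). Ribosomal protein genes had 6 of 87 higher and 10 lower (−0.35, percentile 0.04, but 0.02 under TMM scaling and positive per spike-in count), and mitochondrially encoded genes 2 of 15 higher and 1 lower (0.11, percentile 57.1, with a lower summed level per cell at P2.5, 27509 against 39350 CPM). Germ cell markers had 1 of 6 higher and 1 lower (−0.58, percentile 3.03, positive per spike-in count and with a higher sum at P2.5), with Ddx4 at 546 and 310 CPM (−0.81) and Dazl at 1023 and 627 CPM (−0.71).

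Transcripts of other cell types made up much of the lower end of the comparison. Of the 12 genes with the lowest ratios, Tpsb2, Cma1 and Cpa3, which encode mast cell proteases, stood at 2738, 2492 and 2064 CPM at E17.5, and 85.3% of their summed E17.5 counts lay in library 10. With 0.5 CPM added their log2 ratios were −12.39, −12.28 and −11.98 over all libraries and −9.68, −9.62 and −9.25 without the 4 libraries. Prss34, Hdc, Il1rl1, Car2, Ermap, Rac2 and Fermt3 completed the set with Meioc and Stra8. The erythroid list had 5 of 5 members at least 2-fold lower at P2.5 (median −5.15, percentile 0, and −2.63 per spike-in count), with Hba-a1 at 669 and 18.4 CPM. The granulosa and pregranulosa list had 10 of 12 lower and 1 higher (−2.30, percentile 0.20, and 0.22 per spike-in count), with Fst at 20.9 and 0.961 CPM (−4.45). Its receptor gene Amhr2 stood at 104.7 and 4.28 CPM (−4.61), but at a log2 ratio of 2.00 with E17.5 cells 1 to 10 alone. Immune markers had 3 of 4 lower (−3.15, percentile 2.18, and −0.64 per spike-in count, with summed levels per cell of 3.37 and 9.06 CPM in the median), with Tyrobp at 37.5 and 0.13 CPM and C1qb at 0 counts and 10.6 CPM. Endothelium markers had 2 of 3 lower (−1.94, percentile 15.6), surface epithelium markers 2 of 3 lower and 1 higher (−1.60, percentile 15.3) and stroma markers 2 of 5 lower and 2 higher (−0.44, percentile 59.2), and the medians of these 3 lists were positive per spike-in count.

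**Figure D2:**
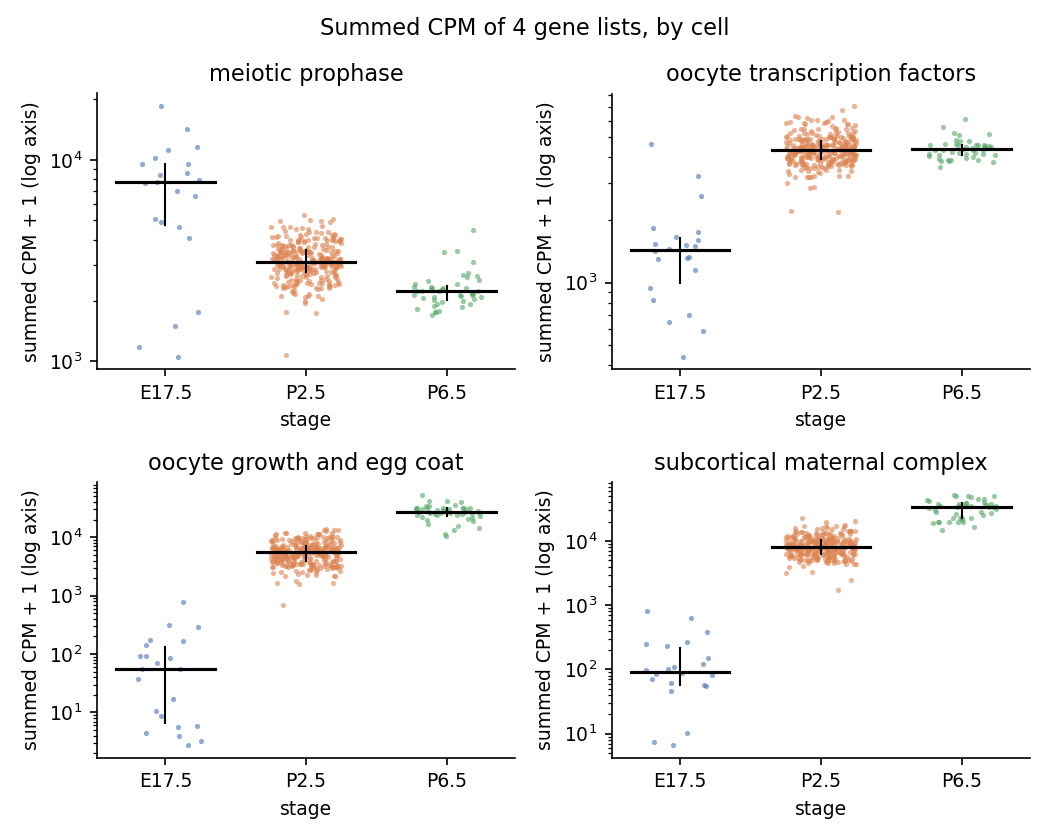
Summed level of the members of 4 gene lists in each cell (points, CPM plus 1, log axis) at the 3 stages; the horizontal line is the median and the vertical line spans the quartiles. Median growth and egg coat levels are 54.9 (154.7 in E17.5 libraries 1 to 10 and 6.25 in libraries 11 to 22), 5504 and 27243 CPM at E17.5, P2.5 and P6.5, and median meiotic prophase levels 7749, 3114 and 2225 CPM, a direction that holds as a share of counts and not for the list median per spike-in count.

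Between P2.5 and P6.5 the same 2 lists stood apart again, with smaller ratios. At P6.5, 24 of 32 growth and egg coat genes and 8 of 9 members of the subcortical maternal complex were at least 2-fold higher than at P2.5, and 0 were at least 2-fold lower. The DNA methylation list was also higher (median log2 ratio 0.56, percentile 99.96), led by the maintenance methyltransferase gene Dnmt1 at 236.8 and 1455 CPM. Mitochondrially encoded, immediate early and meiotic prophase genes were lower at P6.5 as a share of counts and higher per spike-in count. No member of the oocyte transcription factor list differed by 2-fold in either direction as a share of counts, whereas 13 of 13 were at least 2-fold higher at P6.5 per spike-in count.

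The median log2 ratio of all 14643 measured genes, P6.5 over P2.5, was −0.18, and the other scalings moved it by 0.23 (TMM), 0.33 (median-of-ratios), 0.20 (the deposited FPKM) and 2.78 (spike-in). The growth and egg coat list had a median of 1.94 (2.12 relative to all genes, percentile 100) and the subcortical maternal complex list one of 2.40 (2.58 relative to all genes, percentile 100). Summed per cell, the growth list had a median of 5504 CPM at P2.5 (quartiles 3868 to 7014) and 27243 CPM at P6.5 (23461 to 31900). The distributions met at their edges, where 14 P2.5 cells (4.78%, 2.64 to 7.89%) reached the lowest P6.5 cell. Oosp1, which encodes a secreted oocyte protein (ENSMUSG00000041857.10, chromosome 19, 11667460 to 11691150, minus strand), stood at 1.16 and 71.8 CPM, 61.7-fold apart (log2 ratio 5.95, 5.89 to 6.01). Elobl stood at 41.9 and 1423 CPM (5.09), and Zar1, which binds and stores maternal mRNA, at 26.7 and 689 CPM (4.69, 4.68 to 4.70). Kpna7, an oocyte importin gene, stood at 23 and 250.5 CPM (3.45). Nlrp4a (4.29), Oosp2 (3.86), Rasa4, Acp4, Scg3, Olfm1, Ldhd and Rnf182 completed the 12 genes with the largest ratios. At the other end of the complex list, Nlrp4f stood at 867.7 and 906 CPM (0.06) and Nlrp5 at 1818 and 4100 CPM (1.17).

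The DNA methylation list had 2 of 12 members at least 2-fold higher and 0 lower (0.74 relative to all genes). Dnmt1 (ENSMUSG00000004099.16, chromosome 9, 20907209 to 20959888, minus strand) had a log2 ratio of 2.62 (2.61 to 2.62), and its partner gene Uhrf1 stood at 684 and 1850 CPM (1.44). The histone methyltransferase gene Setd2 was lower at P6.5 (−0.82). Among primordial germ cell and pluripotency genes (2 of 12 higher, 1 lower, median −0.44, percentile 22.4, positive per spike-in count and with genes from 10 CPM alone, with per-cell medians of 199.2 and 930 CPM) Dppa5a stood at 110 and 850 CPM (2.95) and Pou5f1 at 25.8 and 103.3 CPM (2.00). The mitotic list had a median of 0.23 (percentile 99.65) with 1 of 22 members at least 2-fold lower and 0 higher, and its Ccnb1 and Ccnb2, both B-type cyclin genes, had log2 ratios of 0.92 and −1.08. Stored mRNA regulators had 4 of 21 higher and 1 lower (0.14, percentile 96.9).

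The mitochondrially encoded list had 5 of 15 members at least 2-fold lower and 0 higher (median −0.89, −0.71 relative to all genes, percentile 0, and 1.89 per spike-in count), with 0 of 15 at least 2-fold lower in the deposited FPKM. Its rRNA gene mt-Rnr2 stood at 10415 and 8428 CPM (−0.31) and the transfer RNA gene mt-Tp at 33.4 and 8.51 CPM (−1.97). Immediate early and heat shock genes had 6 of 15 at least 2-fold lower and 0 higher (−0.78, −0.60 relative to all genes, percentile 0.08, and 2.00 per spike-in count), with Fos at 51.7 and 12.8 CPM (−2.01) and Egr1 at 205.9 and 52.2 CPM (−1.98). The meiotic prophase list had 9 of 34 at least 2-fold lower and 1 higher (−0.59, −0.41 relative to all genes, percentile 0, and 2.19 per spike-in count), and 5 lower under TMM scaling. Meiob, which acts in recombination, stood at 9.15 and 1.56 CPM (−2.56), and Sycp2, of the synaptonemal complex, at 11.4 and 25.9 CPM (1.19). The piRNA list had 1 of 18 lower and 0 higher (−0.47, percentile 0.12, positive per spike-in count), with Piwil4 at 14 and 4.69 CPM (−1.58).

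The genes with the lowest ratios at P6.5 differed less than those with the highest. Nxf2, an mRNA export factor gene, stood at 31.6 and 2.54 CPM (log2 ratio −3.64, −3.72 to −3.55), Tmc2 at 30.2 and 4.76 CPM (−2.66), Psat1, an enzyme gene of serine synthesis, at 153.8 and 31.6 CPM (−2.28) and Mageb4 at 169.5 and 36.3 CPM (−2.22). Fuca2, Tktl1, Snhg11, Yjefn3, Zfp36l1, Tsc22d3, Platr14 and Kyat3 completed the 12.

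Oocyte transcription factors had a median of −0.12 (percentile 39.1), with Nobox, which acts at the start of follicle growth, at 944 and 1352 CPM (0.52) and Taf4b at 108.9 and 71.6 CPM (−0.61). The KIT, PI3K, mTOR and FOXO list had 1 of 25 higher and 0 lower (−0.06, percentile 68.8), cholesterol and lipid synthesis 1 of 18 higher and 0 lower (−0.03, percentile 80.3), glycolysis 1 of 16 higher and 4 lower (−0.13, percentile 45.9), oxidative phosphorylation 0 of 23 on either side (−0.18, percentile 10.5) and ribosomal proteins 2 of 86 lower (−0.13, percentile 8.62). The medians of these lists and of the transcription factors turned positive under TMM, median-of-ratios or spike-in scaling, and the summed level per cell was higher at P6.5 for glycolysis (medians 5123 and 7051 CPM) and for cholesterol and lipid synthesis (1496 and 1604 CPM). Quality control and cell death genes had 2 of 20 lower (−0.29, percentile 19.2, and 0.05 under median-of-ratios scaling), and autophagy genes 0 of 18 on either side (0.08, percentile 90.3). Germ cell markers had a median of 0.08 (percentile 75.4). Of the other cell types, the erythroid list had 4 of 4 members at least 2-fold lower at P6.5 (−2.99, percentile 0, and −0.20 per spike-in count), surface epithelium 2 of 3 lower (−1.89, percentile 0.05, positive per spike-in count), granulosa and pregranulosa 4 of 10 lower and 2 higher (−0.09, percentile 79.5, positive under other scalings, with per-cell medians of 14.6 and 22.8 CPM) and stroma 1 of 7 higher (0.63, percentile 97.6). The stroma median was that of sums in which single cells reached 962 CPM at P6.5, and the per-cell stroma level was lower there (median 1.51 against 12.96 CPM). Fewer than 3 members of the endothelium, immune and perivascular lists were measured.

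Within P2.5, clustering on genes outside all lists split the cells into 4 clusters of 96, 90, 55 and 52 cells (32.8%, 30.7%, 18.8% and 17.7%). The clusters differed in some of the programmes that also separated the stages. Growth and egg coat genes were higher in cluster 3 than in the other P2.5 cells (22 of 30 members, median log2 ratio 0.42) and lower in cluster 4 (27 of 30, −0.73) and cluster 1 (23 of 30, −0.23). Immediate early genes were lower in cluster 2 (14 of 15, −0.71). Cluster 4 also had higher mitochondrially encoded (15 of 15, 0.46) and ribosomal protein genes (83 of 86, 0.28).

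All medians in the clusters are log2 ratios of summed counts against all other P2.5 cells, and members called higher or lower there differ by any amount. Cluster 1 was led by Hba-a1 (45.6 CPM against 8.41 CPM in the other cells), Hbb-bs, Mylpf, Platr14, Fmc1, Pecam1, Pou4f1, D16Ertd472e, Epp13 and Mlf1, and erythroid markers were higher in it (5 of 5, median 1.66). Its subcortical maternal complex median was −0.53 (7 of 8 lower, percentile 0.02), with Padi6 at 2584 against 3929 CPM and Ooep at 297.6 against 536 CPM. Stored mRNA regulators (−0.17), quality control genes (−0.20), ribosomal proteins (−0.09), granulosa markers (−1.19) and surface epithelium markers (−0.86) also had medians under percentile 2.5 in cluster 1. Oxidative phosphorylation (20 of 23 higher, 0.24) and meiotic prophase (24 of 33, 0.21) had higher medians, at percentiles 92.5 and 96.6. Without 8 cells far out on the second principal component (6 in cluster 3 and 2 in cluster 4), a setting chosen after the data were seen, the granulosa median was −0.01 and the surface epithelium median 0.07.

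Cluster 2 was led by Nxf2 (54.8 against 18.9 CPM), Taf7l, Tex19.2, Dusp9, Sp110, Ldha, Tsc22d3, Sdcbp2, Ccdc120 and Cited1. Jun stood at 6.66 against 14.6 CPM in it, Uhrf1 at 881 against 576 CPM and Tet3, which oxidises methylcytosine, at 50.1 against 31.2 CPM. Its medians were 0.11 for meiotic prophase, 0.12 for growth and egg coat, 0.20 for the subcortical maternal complex, 0.20 for DNA methylation, 0.17 for glycolysis and 0.19 for cholesterol and lipid synthesis, all in the upper tail of the random lists. They were −0.14 for oxidative phosphorylation, −0.13 for ribosomal proteins, −1.56 for granulosa, −1.31 for stroma, −0.76 for surface epithelium and −1.53 for erythroid markers, all in the lower tail. Without the 8 far-out cells the medians of granulosa, stroma and surface epithelium markers were −0.56, −0.91 and −0.25, and that of immediate early genes −0.46.

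Cluster 3 was led by Cyr61 (28 against 1.96 CPM), Krt18, Cpe, Clu, Vim, Sdc4, Col3a1, Gstm2, Gstm1 and Sparc, a set with epithelial and stromal genes. Granulosa and pregranulosa markers (9 of 10, median 1.88), stroma markers (5 of 5, 0.96) and surface epithelium markers (5 of 5, 0.73) were higher in it, but without the 8 far-out cells these medians were −0.03 (3 of 7), 0.13 (2 of 4) and 0.45 (3 of 3). The higher growth genes did not depend on those cells (23 of 30, median 0.43 without them). Ooep stood at 877 against 345 CPM, Padi6 at 4820 against 3172 CPM and Oas1c at 463 against 224.2 CPM. Immediate early genes were higher in the sums (13 of 16, median 0.53) but not without the 8 cells (9 of 15, 0.03). Among them Ier3 stood at 7.73 against 0.782 CPM in the sums, with a per-cell median of 0.104 CPM in cluster 3. The subcortical maternal complex had a median of 0.25, and mitochondrially encoded (−0.32), meiotic prophase (−0.22), oxidative phosphorylation (−0.14) and erythroid marker genes (−1.36) had lower ones. Under 6 of 9 other clustering settings cluster 3 had no counterpart of its own and shared its best match with another cluster. With 10 principal components that shared match, mostly of clusters 3 and 4, had 6 growth genes higher. With double the number of variable genes cluster 3 kept a match of its own, in which only a minority of growth genes were higher.

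Cluster 4 was led by Lars2 (1869 against 476 CPM), Mt1, Isg20, Nfkbiz, Kcnt1, Zfp651, Hao2, Egr2, Ccpg1 and Dusp5. Npm2, which encodes a histone chaperone of the egg (ENSMUSG00000047911.6, chromosome 14, 70647302 to 70659244, minus strand), stood at 42 against 202.6 CPM in it (log2 ratio −2.27), Padi6 at 2172 against 3789 CPM and the gap junction gene Gja4 at 322 against 280.8 CPM. The subcortical maternal complex (7 of 8, −0.40), piRNA pathway (16 of 18, −0.42), pluripotency (9 of 13, −0.40), glycolysis (15 of 17, −0.33), cholesterol and lipid synthesis (15 of 18, −0.31), mitotic (20 of 22, −0.28) and meiotic (25 of 34, −0.17) lists were lower, and the KIT, PI3K, mTOR and FOXO list had a median of 0.14 with members on both sides (14 of 25 higher). Without the 8 far-out cells, 2 of them in this cluster, the growth median was −0.72, and granulosa and immediate early medians were 0.67 and 0.48 in place of 0.09 and 0.09. The kinase gene Stk11 stood at 27.3 against 14.4 CPM and the mitochondrial rRNA gene mt-Rnr1 at 1391 against 613 CPM. Cytoplasmic and mitochondrial rRNA together took a median of 9.80% of counts in its cells, against 2.77%, 5.98% and 5.93% in clusters 1 to 3. At resolution 0.3 the cells of clusters 2 and 3 and most of cluster 4 fell into 1 cluster, and cluster 4 shared its best match with another cluster in 3 of the 9 settings.

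**Figure D3:**
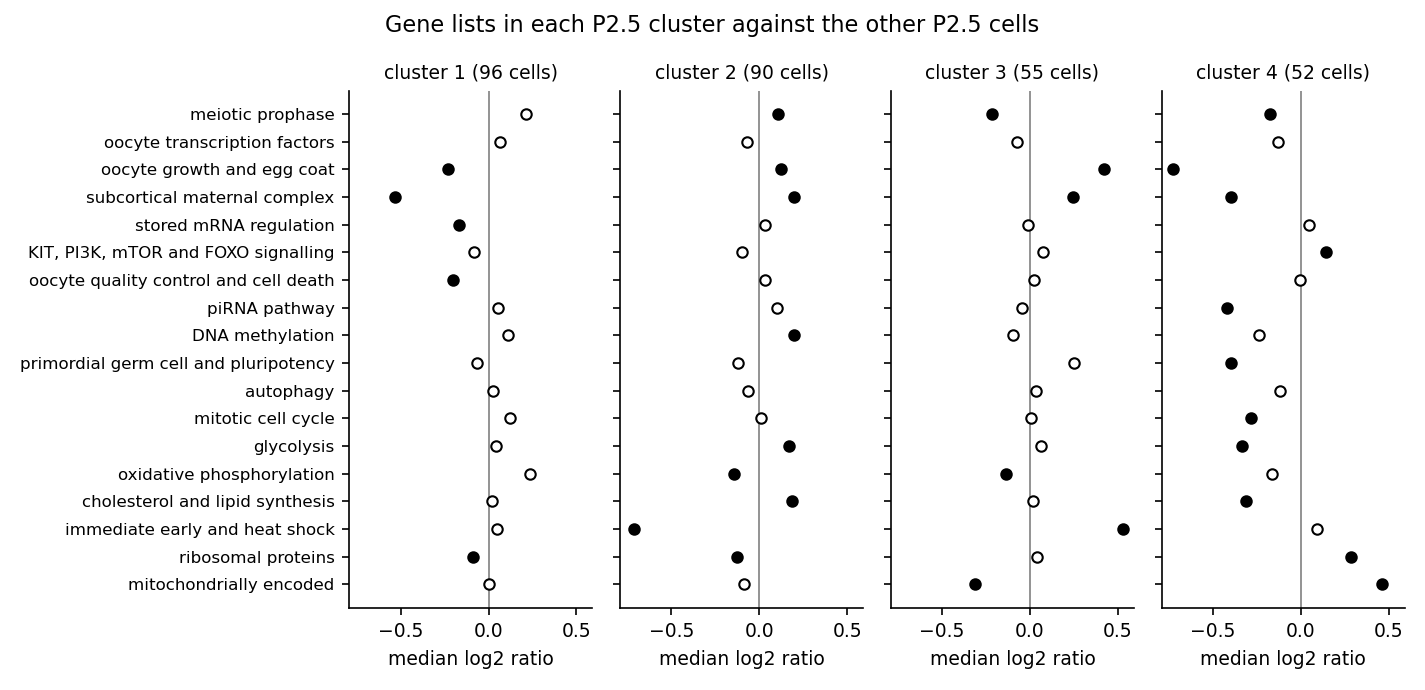
Median log2 ratio of 18 gene lists in each of the 4 P2.5 clusters (1 panel each) against all other P2.5 cells; filled circles mark medians in the lowest or highest 2.5% of 10000 random matched lists and open circles the rest. The growth and egg coat median is −0.23, 0.12, 0.42 and −0.73 in clusters 1 to 4, and the higher immediate early median of cluster 3 (0.53) is 0.03 without 8 far-out cells.

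None of the markers fixed for oocyte states was among the 10 leading genes of a cluster, so the clusters were kept by number. The growing oocyte markers had medians of −0.47, 0.09, 0.49 and −0.65 in clusters 1 to 4, the primordial follicle oocyte markers of 0.01, 0.05, −0.01 and −0.12, and the meiotic prophase markers of 0.21, 0.13, −0.23 and −0.08. Against the other stages, the growth and egg coat list had medians of 4.53, 4.16, 4.23 and 4.13 over E17.5 and of −2.13, −1.73, −1.56 and −2.47 over P6.5. Across genes outside the lists, which are not independent replicates, the Spearman correlation of the cluster level with the E17.5 level was 0.75 to 0.762 and with the P6.5 level 0.945 to 0.970. Simulated cells with no planted difference were also split into 2 clusters, so the number of clusters is no evidence of distinct cell states.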

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

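The settings that use 1 library of each pair, leave out rRNA rows or the 4 E17.5 libraries, take E17.5 cells 1 to 10 or 11 to 22 alone, scale to spike-ins, cluster pairs apart or leave out far-out P2.5 cells were chosen after the data were seen, and the others before. Of the values of 28 counts that answer a comparison, 358 lay within 1.5 times of the reported count and 51 did not. Some of the 358 could not have moved. The setting with all deposited cells repeats the main one, because the filter removed 0 cells, and settings on E17.5 cells leave P6.5 over P2.5 unchanged. Of the values for named genes and for the other list counts by stage, 3170 were called the same, 2209 moved and 7, of genes at least 2-fold apart, changed sign. A named gene was called the same within its counting interval, and a list count within 1.5 times. Genes with smaller ratios that changed sign, such as Fmn2 (−0.26 with E17.5 cells 11 to 22), are among the 2209. No paired analysis was possible because the number in a cell's name only names the cell. Depth limits genes with few counts at E17.5, the stage with fewest cells. The cause was not tested for any value here except spike-in scaling, which adds 1 shift to every gene.

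Meiotic prophase genes at least 2-fold lower at P6.5 numbered 9, and 5 with 5 CPM added, 5 under TMM, 5 in FPKM, 4 under median-of-ratios and 0 per spike-in count. Mitochondrially encoded genes lower at P6.5 numbered 5, and 3 under TMM, 3 under median-of-ratios, 0 in FPKM, 8 with cells thinned, 8 by the mean over cells and 0 per spike-in count. Immediate early genes lower at P6.5 numbered 6, and 3 with 5 CPM added, 3 with at least 10 CPM and 0 per spike-in count. DNA methylation genes higher at P6.5 numbered 2, and 4 in FPKM, 5 under median-of-ratios and 12 per spike-in count. At P2.5 against E17.5, spike-in scaling gave 10 lower meiotic prophase genes in place of 24, 14 higher transcription factors in place of 8, and 2 lower glycolysis genes, 1 lower cholesterol gene and 2 lower immediate early genes in place of 10, 9 and 10. Lower cholesterol genes numbered 4 with E17.5 cells 1 to 10, 5 in FPKM and 3 without the 4 libraries, which also left 6 lower glycolysis genes. The cause was not tested.

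With E17.5 cells 1 to 10 alone the log2 ratio changed sign for Gabarapl1 (0.14), Rps10 (1.81), Krt18 (1.96), Amhr2 (2.00) and Col3a1 (3.94). It did so for Cd68 (0.53) with cells 11 to 22 and for Eif4ebp2 (0.22) without the 4 libraries. The cause was not tested.

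The 4 P2.5 clusters became 2 at resolution 0.3 and 7 at resolution 1.0. Each cluster was matched to the new cluster with the largest overlap, and 2 or more clusters often shared a match, so the numbers then describe 1 merged cluster. At resolution 0.3 clusters 2, 3 and 4 shared a match. It had 9 lower and 6 higher immediate early genes (14 lower reported for cluster 2 and 13 higher for cluster 3) and, against the numbers for cluster 4, 7 lower growth genes (27), 1 lower maternal complex gene (7), 9 lower piRNA genes (16), 8 lower glycolysis genes (15), 9 lower cholesterol genes (15), 50 higher ribosomal protein genes (83) and 7 higher mitochondrially encoded genes (15). With 10 principal components clusters 3 and 4 shared a match with 6 higher growth genes (22 in cluster 3) and 7 lower and 8 higher mitochondrially encoded genes (11 lower in cluster 3, 15 higher in cluster 4). Without rRNA rows clusters 3 and 4 shared a match made mostly of cluster 4 cells, with 6 higher growth genes, 5 lower and 8 higher mitochondrially encoded genes, 9 lower glycolysis genes and 9 lower cholesterol genes. With 30 neighbours clusters 2 and 3 shared a match with 8 lower and 7 higher immediate early genes. Clusters 2 and 3 also shared a match with cells thinned and with pairs clustered apart, where 2 and 1 immediate early genes were higher. Cluster 3 had a match of its own, with 4 higher immediate early genes, at resolution 1.0, and one with 11 higher growth genes with double the number of variable genes. The cause was not tested.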

Other observations

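All tests given here were chosen after the result was seen, except the test of transcript length.

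Genes of oocyte growth had reached different parts of their P6.5 level by P2.5. Of 29 growth and egg coat genes with at least 5 CPM at 1 or more of the stages, 6 stood at P2.5 at 50% or more of that level and 4 under 10%, and of 9 subcortical maternal complex genes 1 and 2 did. At the late end Oosp1 stood at 1.62% of its P6.5 level, Nlrp4a at 5.13%, Nlrp9a at 5.97%, Nlrp2 at 6.31% and Oosp2 at 6.89%. At the early end Fmn2 stood at 143.4%, so it was lower at P6.5 as a share of counts, Nlrp4f stood at 95.7%, Fbxw18 at 66.3%, Gja4 at 63.7% and Nlrp4c at 62.1%. Zp3 and Zp2, the egg coat genes (16% and 17.1%), the growth factor gene Gdf9 (19%) and Padi6 (19%) lay between. These are shares of counts. Per spike-in count 0 genes of either list reached 50%, 28 of 29 and 8 of 9 lay under 10%, and Fmn2 stood at 20.8%. No explanation was tested.

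X-linked genes, looked at after their names were seen to recur, were lower at P6.5 than at P2.5. Over 537 measured X-linked genes the median log2 ratio was −0.40, under all 10000 random lists and the lowest of 20 chromosomes, the next being chromosome 13 at −0.29. With genes from 5 CPM it was −0.34 over 381 genes, against −0.24 for chromosome 16. At P2.5 over E17.5 the X-linked median of −0.562 was also the lowest, but chromosome 3 lay beside it at −0.557. X-linked genes took a median of 3.53%, 3.25% and 2.93% of counts per cell at the 3 stages, and of 3.40%, 3.32%, 3.14% and 3.02% in P2.5 clusters 1 to 4. Of the 10 leading genes of P2.5 cluster 2, 6 were X-linked (Nxf2, Taf7l, Dusp9, Tsc22d3, Ccdc120 and Cited1), against 0 of those of cluster 1, where the X-linked share was highest, and Xist stood at 129.6, 5.55 and 0.777 CPM at the 3 stages. At E17.5 Xist stood at 204.8, 440, 542 and 269.9 CPM in libraries 8, 10, 15 and 16, which were low in germ cell markers, against a median of 37.4 CPM in the other 18. The directions at P6.5 are shares of counts and turn positive per spike-in count. No explanation was tested.

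The first pattern weighed is the presence of mast cell genes in E17.5 libraries 1 to 9, where 12 such genes took 0.166% to 1.5% of counts, against 12.5% in library 10 and at most 0.0240% in libraries 11 to 22. For 47 genes above 200 CPM in library 10 and below 1 CPM in each of libraries 11 to 22, the share of its counts found in libraries 1 to 9 was nearly constant. The upper quartile of that share was 1.22 times the lower in the median library, as carry-over of material or barcodes from library 10 would give. In library 10, 26 germ cell and meiotic genes appeared at a median of 1.61% of their summed counts in libraries 1 to 9. That value cannot tell carry-over into library 10 from background, because libraries 15 and 16, also low in germ cell markers, held similar levels. The meiotic list stood at 1050.5 CPM in library 10 and at 1172 and 1759 CPM in libraries 15 and 16. Whether such carry-over arose at the bench or in read assignment stays open, and no biological explanation was tested. The origin of the E17.5 counts of Padi6, all in libraries 1 to 10, was not tested. These libraries also had a higher growth and egg coat level (median 154.7 CPM against 6.25 CPM in libraries 11 to 22). The values argue against carry-over among libraries 1 to 10 alone as the source of that level. Library 3, the highest at 787.6 CPM, would have no source among them, and the lowest of them stood at 70.3 CPM. The shares of library 10's counts found in libraries 1 to 9 had medians of only 1.04% to 4.68%. A source outside libraries 1 to 10 was not tested.

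The second pattern is the low level of germ cell markers in E17.5 libraries 8, 10, 15 and 16. The tables argue against low RNA yield, because 0 of the 4 lay below the median of the other 18 libraries in counts per spike-in count (143.2, 127.7, 129.6 and 85.9 against 76.5). A mast cell is a candidate source for library 10, where 6 of 6 mast cell genes not seen at the top of the stage comparison had their highest level (Tpsab1 5304, Mcpt4 6200, Ms4a2 294.2, Fcer1g 900, Srgn 2803 and Gata2 1978 CPM), and a granulosa lineage cell for library 16, with 13.6 times the median marker level of the other libraries, although libraries 18 and 19, at 1980 and 1424 CPM, were as high. Libraries 8 and 15 had high Klf1 (676 and 545 CPM against 25.9) and Ermap (611 and 621 against 16.6), genes chosen after their values were seen, but the higher of their erythroid list levels was only 1.15 times the median, so red cells cannot be told apart from other sources. The hand picking named in the labels would leave out such cells only by eye, and no biological explanation was tested.

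The third pattern is the lower growth and egg coat list in P2.5 cluster 4, at a median of −0.73. The tables argue against dilution of counts by rRNA and unequal weight of deep cells as the source of this median. It was −0.65 with rRNA rows left out of the counts and −0.76 with each cell thinned to 1 depth. Both settings kept the same cells in the cluster, and an rRNA share of 9.80% could shift a ratio only slightly. They therefore do not show whether rRNA, depth or RNA quality set these cells apart. Loss of long transcripts would have raised this list, whose members had a median exonic length of 1834.5 bases against 3970.5 for all measured genes, so its percentile of 0 among random lists matched on expression and length adds nothing against that cause beyond the direction. Cells of this cluster may differ from the rest in how far oocyte growth genes had come on, or in RNA quality, of which their higher rRNA share of 9.80% is 1 sign that was not tested further. The labels give no group within P2.5, so no biological explanation was tested, and at resolution 0.3 the cluster merged with others and 7 growth genes were lower.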
